A study of Arabidopsis thaliana with 12 samples.

How the data were processed

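The study measured messenger RNA from leaves of 5-week-old Arabidopsis thaliana on 12 one-colour Affymetrix arrays. Per the labels, the plants were wild type Columbia-0 (Col-0) or the heterozygous activation mutant gh3.5-1D, and leaves were taken uninoculated or 48 h after inoculation with Pseudomonas syringae pv. tomato DC3000 carrying avrRpt2, a bacterium that delivers an effector recognised by Col-0. Each of the 4 groups held 3 arrays that the labels call biological replicates, so the p-value of a single gene covers the spread between these biological replicates as labelled. The uninoculated leaves were taken at the start, and no mock-inoculated leaves were analysed here, so an infection contrast also spans the inoculation, the handling and 48 h of time. Per the labels' protocols, total RNA was purified, copied to cDNA and labelled with biotin.

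The authors deposited 1 intensity per probe set and array on a linear scale, made with GCOS 1.4 per the submitters' processing notes. The values themselves showed the scaling: the trimmed mean over all probe sets was 100.01 on every array, while the median signal ran from 21.6 to 27.5 on the Col-0 arrays and from 28.7 to 31.1 on the gh3.5-1D arrays. Scanner images, probe-level intensities and detection calls were not used here, so probe-level background correction and summarisation could not be changed. For arrays the number of replicates limits the precision. No 2 arrays held identical values, and every column of the table was matched to 1 sample by its label.

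The table held 22810 probe sets. The 64 control probe sets were left out, and of the other 22746 the annotation table gave 1 gene for 13513, several genes for 503 and none for 8730, which are unnamed here rather than without a gene. Of the single-gene probe sets, 13436 matched a gene of the RefSeq table used for current names. No probe set with several genes was named, and coordinates are not printed because the build behind the annotation was not given in the sources used here. Genes of near-identical sequence, such as PDF1.2 and PDF1.2b, may share signal on these probe sets.

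From the deposited intensities, log2(signal + 5) was computed, where 5 is the rounded 20th percentile of the table. All fold changes are on this scale, which understates the change of dim genes. A probe set was kept when at least 3 of the 12 arrays exceeded 16.1, the 40th percentile. This kept 15376 probe sets and left out 7370, and 8446 of those kept named 1 gene each, 8352 different genes together. Below, a count of genes is a count of probe sets, and a gene with several probe sets was represented by the one with the highest mean.

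Differences were tested with limma 3.58.1 in R 4.3.3. One model held the 4 group means over the 12 arrays with 8 residual degrees of freedom, variances were moderated with eBayes and an intensity trend (median prior degrees of freedom 10.6), and tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over the 15376 probe sets, and a gene was called at an adjusted p under 0.05. The contrasts were infection in Col-0, infection in gh3.5-1D, genotype without inoculation, genotype at 48 h, the difference of the infection response between the genotypes, and the genotype difference averaged over both times. Errors of log2 changes are limma standard errors, and errors of signals are standard deviations over 3 arrays.

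Lists of genes were tested against all other genes with camera at a preset correlation of 0.01, then with an estimated correlation, and by themselves with fry. A camera p-value at the preset correlation rests on the spread across genes, taken as nearly independent, and does not measure the spread between replicates. Before the data were examined, the groups, the contrasts, the tests, the alternatives and 25 lists with 445 genes were fixed. The annotation named a probe set for 63 of those genes and the filter kept 51, so most fixed lists are represented by few members. Of the fixed lists, 7 had at least the 3 kept genes needed for a test and 6 had no kept gene. A further 18 lists were written after the annotation was read and before any group comparison was computed, and 24 lists in all were tested as sets, with adjustment over those 24. None of the 24 lists in any contrast stayed past the threshold with an estimated correlation.

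The genes named in the text follow a rule fixed before the data were examined. It names GH3.5 and the GH3 family, and per contrast the 6 largest rises and 6 largest falls among called genes with 1 gene per probe set. For contrasts of 2 groups, the 3 arrays of one group had also to lie beyond the 3 of the other, which chance gives for 10% of genes. It also names up to 4 called members with the largest change per fixed list, and a set of defence, hormone and clock genes whichever way they go, of which only PDF1.2 and IAA29 had a kept, named probe set. The same naming rule was applied to the 18 lists added later. Of genes that fit the rule, the report gives mainly those whose call held in all 12 fits that leave out 1 array.

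Agreement of 2 contrasts that share no array was described by Pearson and Spearman correlations across genes, which are not independent replicates, and by the overlap of calls beside the number independent lists would share. Signs of RNA quality were the log2 ratios of 3' to 5' signal of control transcripts, compared with exact permutation tests, two-sided, whose smallest possible p for 3 against 3 arrays is 0.1.

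The labels number the replicates 1 to 3 in every group without saying that a number marks a shared batch. Arrays of equal number were checked for shared deviations from their group means. The correlations were 0.108, 0.24 and 0.317 for the 3 pairs of Col-0 arrays, all over 0.1. The numbers were therefore taken to pair the arrays of the infection contrast in Col-0, on the evidence of these values alone. The main fit, fixed beforehand, leaves this pairing out, and gene calls and list tests of that contrast come from the unpaired fit. The count with the replicate number as a block is given beside it.

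The model, the contrasts and camera were tested on simulated data with 200 changed genes among 15376 per contrast. The noise was drawn independently for each gene, so deviations that genes share within an array are left out of the rates below. A planted list gave camera p-values of 1.02e-23 to 1.32e-08. With independent noise this does not test camera at the preset correlation on lists of correlated genes. A log2 change of 2 was recovered for 84% of changed genes for infection in Col-0, 79.5% for infection in gh3.5-1D, 75.5% for genotype without inoculation, 77.5% for genotype at 48 h and 52% for the difference of the infection response. A log2 change of 1 was recovered for 6.5%, 6.5%, 8%, 13.5% and 0.5% of them in the same order, so changes of that size are mostly missed when they are few.

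The alternatives were pseudocounts of 0 and 20, no filter and a floor of 45.4, quantile normalisation, median centring, eBayes without the trend or robust, array quality weights, the replicate number as a block, only the 2 groups compared in the model, stricter thresholds, and each array left out in turn. Leaving out the 4 arrays numbered 3, or the 2 Col-0 arrays numbered 3, was added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.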

Results

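Leaf RNA of 5-week-old Arabidopsis plants was profiled on 12 arrays in 4 groups of 3: Col-0 and gh3.5-1D, each uninoculated and 48 h after inoculation with Pseudomonas syringae carrying avrRpt2. The mutant gh3.5-1D is heterozygous for an activated allele of GH3.5, which encodes an acyl acid amido synthetase that joins amino acids to auxin and acts on salicylic acid. The design asks how each genotype changed after inoculation, how the genotypes differed at each time, and whether the change after inoculation differed between them. After the filter, 15376 probe sets were tested, and the counts of genes below are counts of these. Of the 22746 probe sets that are not controls, 13513 carry a single gene name, and genes are named only from those, so each largest change is the largest among them. The order of changes holds at the pseudocount of 5 and turns for some genes at another. The first principal component held 40.2% of the variance and separated uninoculated from inoculated arrays, with scores of at most -41.7 in the former and at least 7.4 in the latter. The second held 25% and lay higher in Col-0 (6.3 to 68.5) than in gh3.5-1D (-58.3 to -19.6).

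GH3.5 (AT4G27260, listed as WES1 in the annotation) was strongly raised in the mutant at both times. Its mean signal was 10.1 ± 5.7 in uninoculated Col-0 and 3420 ± 244 in uninoculated gh3.5-1D (SD, n = 3), a log2 difference of 7.90 ± 0.36 (SE, limma adjusted p = 1.17e-10). At 48 h the means were 14.4 ± 10.1 and 3150 ± 251 (SD, n = 3), a log2 difference of 7.51 ± 0.36 (SE, limma adjusted p = 2.89e-10). All 6 mutant arrays lay above all 6 Col-0 arrays, whose signals of 3.4 to 23.2 lay near or below the floor of 16.1, so the size of the fold rests on the pseudocount. GH3.5 did not pass the test for infection in Col-0 (log2 change 0.27, adjusted p = 0.72) or in gh3.5-1D (-0.12, adjusted p = 0.853). Among the other measured family members, GH3.9 and GH3.17 passed the threshold in none of the 6 contrasts. GH3.3, an auxin-conjugating relative, was higher in gh3.5-1D at 48 h by 2.49 ± 0.42 (log2, SE, adjusted p = 0.000428), with 133 ± 16.6 against 19.8 ± 5.2 (mean signal, SD, n = 3).

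**Figure D1:**
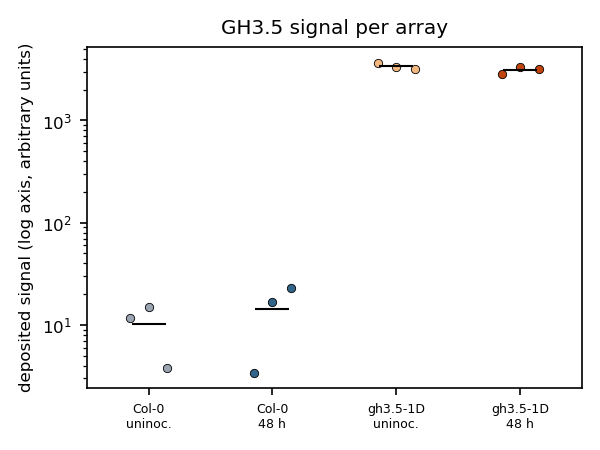
GH3.5 signal of each array (points, log axis, arbitrary units) in the 4 groups, with a bar at each group mean of 3 arrays. The Col-0 arrays lie between 3.4 and 23.2 and the gh3.5-1D arrays between 2872.6 and 3692.2.

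In Col-0, the largest rises 48 h after inoculation were those of AT4G12490, a lipid transfer family protein (log2 change 6.47 ± 0.32, SE, adjusted p = 2.45e-10), the chitinase CHI (4.98 ± 0.34, adjusted p = 2.66e-08), the defensin PDF1.4 (4.84 ± 0.36, adjusted p = 9.04e-08) and AT3G18250 (4.67 ± 0.36). AT4G12500, a relative of AT4G12490, rose by 4.38 and AT1G68620 by 4.14. The largest falls were those of AT3G16670 (-3.63 ± 0.38, adjusted p = 3.95e-06), the thionin THI2.2 (-2.40 ± 0.39) and AT3G05730 (-2.35 ± 0.43). AT1G69523 (-2.32), AT4G18970 (-2.29) and AT5G12050 (-2.27) followed. CHI signal went from 35.8 ± 20.6 to 1170 ± 180 (mean, SD, n = 3).

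Of the 4 measured immune receptor and early signalling genes, 2 rose in Col-0, over all genes and adjusted over the list alone: BIK1, a receptor-associated kinase (1.69, adjusted p = 0.000403), and PUB24, a U-box ubiquitin ligase (1.402, adjusted p = 0.00138). The list rose as a set (mean log2 change 1.15, camera adjusted p = 0.00292), with an adjusted p = 0.109 with an estimated correlation and 0.000914 to 0.109 over 25 camera alternatives. Of 3 chaperones of the endoplasmic reticulum, ERDJ3B rose (0.98, adjusted p = 0.00544), and 2 rose adjusted over the list alone. That set shift (camera adjusted p = 0.033, adjusted p = 0.349 with an estimated correlation, 0.0128 to 0.349 over 25 camera alternatives) was called in 18 of those. Its mean of 0.68 became 0.39 without Col-0 48 h replicate 3 and 0.57 without Col-0 uninoculated replicate 2, both no longer past the threshold. Of 3 salicylic acid genes, BSMT1, a methyltransferase of salicylic and benzoic acid, fell (-1.97, adjusted p = 0.00518), and the transcription factor WRKY53 rose (1.68, adjusted p = 0.0076, but 1.48 and not past the threshold without Col-0 48 h replicate 2). JMT, which methylates jasmonic acid, fell (-1.92, adjusted p = 0.000555). CCL, of 2 clock genes, rose (1.38), while none of 3 reference genes passed the test. Of 4 GH3 genes only GH3.3 was called (1.62, adjusted p = 0.0202), but not without Col-0 uninoculated replicate 1 (1.402), Col-0 uninoculated replicate 2 (1.44) or Col-0 48 h replicate 1 (1.47). The photosynthesis genes of the list fixed beforehand were not shifted as a set (11 measured, 1 fell, 3 fell adjusted over the list alone, mean -0.27, camera adjusted p = 0.114), nor were expansins and xyloglucan endotransglucosylases (4 measured, 1 fell, 2 fell adjusted over the list alone, camera adjusted p = 0.139). Neither fall was kept in all 12 fits that leave out 1 array: that of SBPASE (-0.77, adjusted p = 0.0193) was lost without Col-0 uninoculated replicate 1 (-0.70) or 2 (-0.77) or Col-0 48 h replicate 2 (-0.61, adjusted p = 0.121). That of EXPA16 (-1.23, adjusted p = 0.0356) was kept in 4, those without Col-0 uninoculated replicate 3, Col-0 48 h replicate 3, or gh3.5-1D 48 h replicate 2 or 3. In the other 8 it ran from -1.24 to -0.99, with an adjusted p of up to 0.165.

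In all, 1228 genes were called for infection in Col-0, 713 higher and 515 lower. The count fell to 652 without Col-0 48 h replicate 2, 726 without Col-0 uninoculated replicate 2 and 802 without Col-0 uninoculated replicate 1, and rose to 2573 without Col-0 48 h replicate 3, where lower genes were the majority (1008 higher and 1565 lower). These fits leave out the pairing by replicate number. With the replicate number as a block 1767 genes were called, 933 higher and 834 lower.

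In gh3.5-1D the same contrast gave larger lists on both sides. AT4G12490 rose by 8.01 ± 0.32 (log2, SE, adjusted p = 5.35e-12), the osmotin-like OSM34 by 7.37 ± 0.40 (adjusted p = 3.24e-10), AT4G16260, of the beta-1,3-glucanase family, by 6.38 ± 0.60 (adjusted p = 1.94e-07). AT3G18250, AT4G12500 and CHI rose by 6.18, 6.18 and 6.16. The largest falls were those of AT5G48490, a lipid transfer protein (-5.62 ± 0.45, adjusted p = 2.52e-08), AT2G10940 (-4.94 ± 0.34, adjusted p = 4.31e-09) and AT1G67750, a pectate lyase (-4.85 ± 0.40, adjusted p = 4.3e-08). AT3G05730 (-4.55), AT3G16670 (-3.65) and AT5G12050 (-3.49) followed. CHI signal reached 3117.3 ± 284.9 from 41.0 ± 19.9, and that of OSM34 1396.4 ± 374.5 from 3.6 ± 2.8 (mean, SD, n = 3).

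Of the 4 immune receptor and signalling genes, 3 rose in gh3.5-1D, over all genes and adjusted over the list alone: BIK1 (2.59, adjusted p = 5.61e-07), PUB24 (2.05, adjusted p = 4.89e-06) and PUB23 (1.92, adjusted p = 0.0025). The set shift had a camera adjusted p = 0.00244, with an adjusted p = 0.152 with an estimated correlation and 0.00107 to 0.152 over 25 camera alternatives. Of 11 photosynthesis genes 2 fell, over all genes and adjusted over the list alone, the Calvin cycle enzymes SBPASE (-1.53, adjusted p = 9.1e-06) and PRK (-0.90, adjusted p = 0.00533). As a set they fell (mean -0.49, camera adjusted p = 0.0247, adjusted p = 0.385 with an estimated correlation, 0.0168 to 0.385 over 25 camera alternatives), but not after quantile normalisation (mean -0.34) or without gh3.5-1D 48 h replicate 1 (mean -0.41). Both measured senescence genes rose, SAG29 (3.198) and WRKY6 (2.69), as did ZAT10, a zinc finger regulator of early stress responses (4.61, adjusted p = 4.57e-08), and WRKY53 (3.16). GH3.3 rose by 3.99 (adjusted p = 7.81e-07). Of 4 expansins and xyloglucan endotransglucosylases, EXPA8 (-2.81) and EXPA16 (-2.50) fell and EXPA4 rose (1.47). The auxin-responsive repressor IAA29 fell (-2.13, adjusted p = 6.29e-05), and so did GC1, a guard cell marker (-1.41, adjusted p = 0.00304), of 2 guard cell markers measured. None of 3 reference genes passed the test (median 0.23, mean -0.05). The endoplasmic reticulum chaperones were not shifted as a set (3 measured, 1 rose, 2 rose adjusted over the list alone, camera adjusted p = 0.0844), nor were the GH3 genes (4 measured, 1 rose, 0.199), the salicylic acid genes (3 measured, 1 rose, 0.199) or the expansins and xyloglucan endotransglucosylases (0.197).

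In all, 4071 genes were called for infection in gh3.5-1D, 2012 higher and 2059 lower, and no single array moved that count by over 1.5 times. Of 5 control ratios, the log2 3' to 5' ratio of 1 GAPDH control was higher at 48 h than in uninoculated gh3.5-1D by 0.20 (0.95 against 0.75, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 can give). The second GAPDH control differed by 0.07 (n = 3, exact permutation p = 0.8), and the other 3 ratios gave exact permutation p of 0.5 and 0.6.

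The infection contrasts of the genotypes share no array and ran largely in the same direction. Over 15376 genes the log2 changes correlated with Pearson r = 0.708 and Spearman rho = 0.602, across genes, which are not independent replicates. Both genotypes called 635 genes higher, where independent lists would share 93.3, and 382 lower, where they would share 69. Only 6 genes were called in opposite directions. Both contrasts take the variance of each gene from the same fit, so their calls are not independent. Of the 1228 genes called in Col-0, 1201 (97.8%) had the same sign in gh3.5-1D and 811 (66%) a larger change there. The correlation was 0.601 without the filter, and 0.626 without the Col-0 arrays numbered 3, a setting chosen after seeing the data.

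**Figure D2:**
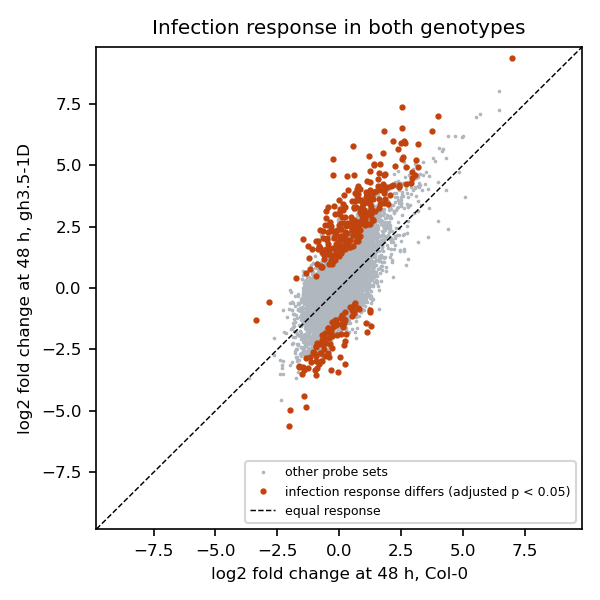
Log2 change after infection in Col-0 (horizontal axis) against that in gh3.5-1D (vertical axis), 1 point per probe set, with a dashed line of equal change. Red points are the 344 genes whose change differed between the genotypes, 256 with a higher and 88 with a lower value in gh3.5-1D.

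Of the genes whose response differed between the genotypes, those with a stronger rise in gh3.5-1D included OSM34, whose infection change exceeded that in Col-0 by 4.84 ± 0.57 (log2, SE, adjusted p = 0.000223). AT4G16260 followed with a difference of 4.56 ± 0.84 (adjusted p = 0.00602), AT1G09500 with 4.204 ± 0.55 (adjusted p = 0.000501), ZAT10 with 3.995 ± 0.54 (adjusted p = 0.000704), AT4G39670 with 3.73 ± 0.59 and AT1G30700, of the berberine bridge enzyme family, with 3.59 ± 0.59. The chitinase ChiC (2.79 ± 0.50, adjusted p = 0.00512) also differed. At 48 h the mean signal of ZAT10 was 114.1 ± 35.9 in Col-0 and 1104 ± 451.8 in gh3.5-1D (SD, n = 3). OSM34, AT4G39670 and AT1G30700 had mean uninoculated signals of 1.4 to 5.9, and AT4G16260 of 0.5 in gh3.5-1D, where the fold depends on the pseudocount. With pseudocounts of 0 and 20 the difference was 7.069 and 3.483 for AT4G16260 and 5.788 and 4.282 for OSM34.

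Genes with a stronger fall in gh3.5-1D included AT5G48490 (-3.61 ± 0.64, adjusted p = 0.00447), AT1G67750 (-3.50 ± 0.57, adjusted p = 0.00267), AT5G20740 (-3.02 ± 0.42, adjusted p = 0.00102), AT2G10940 (-2.95 ± 0.49, adjusted p = 0.00285) and the expansin EXPA8 (-2.41 ± 0.49, adjusted p = 0.0107). EXPA8 signal went from 1865 ± 1030.3 to 1296.1 ± 134.6 in Col-0 and from 559.5 ± 78.8 to 83.7 ± 51.5 in gh3.5-1D (mean, SD, n = 3). GH3.3 passed the threshold (2.37 ± 0.59, adjusted p = 0.039), but not without Col-0 uninoculated replicate 3 (1.97), Col-0 48 h replicate 1 (2.52) or 2 (2.21), gh3.5-1D uninoculated replicate 1 (2.06) or 3 (2.39), or gh3.5-1D 48 h replicate 1 (2.29), 2 (2.47) or 3 (2.34). GH3.5 itself did not differ in response (-0.39, adjusted p = 0.835). CHI (1.18, adjusted p = 0.26), BIK1 (0.90, adjusted p = 0.276) and PUB24 (0.65, adjusted p = 0.456), which rose in both genotypes, were not called for a difference. No list fixed beforehand was shifted as a set, the photosynthesis genes with camera adjusted p = 0.15, the immune genes with 0.15, the salicylic acid genes with 0.152, and the others with at least 0.559. Adjusted over the list alone, 2 salicylic acid genes of 3 had a higher response in gh3.5-1D, against 0 over all genes. The endoplasmic reticulum chaperones had a median of -0.13 and a mean of 0.03, and the reference genes a median of -0.02 and a mean of 0.06.

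The 344 genes split into 256 with a higher and 88 with a lower response in gh3.5-1D. Of the 256, 166 rose in gh3.5-1D without a call in Col-0 and 81 rose in both. Of the 88, 61 fell in gh3.5-1D without a call in Col-0 and 23 fell in both. The count was 705 without Col-0 48 h replicate 3 and ranged from 175 to 229 without gh3.5-1D 48 h replicate 1 (175), Col-0 48 h replicate 1 (201), Col-0 uninoculated replicate 1 (207), gh3.5-1D uninoculated replicate 1 (209), gh3.5-1D 48 h replicate 2 (218) or Col-0 uninoculated replicate 2 (229). The share of higher responses was 74.4% as deposited, 65.8% after quantile normalisation and 76.2% after median centring.

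**Figure D3:**
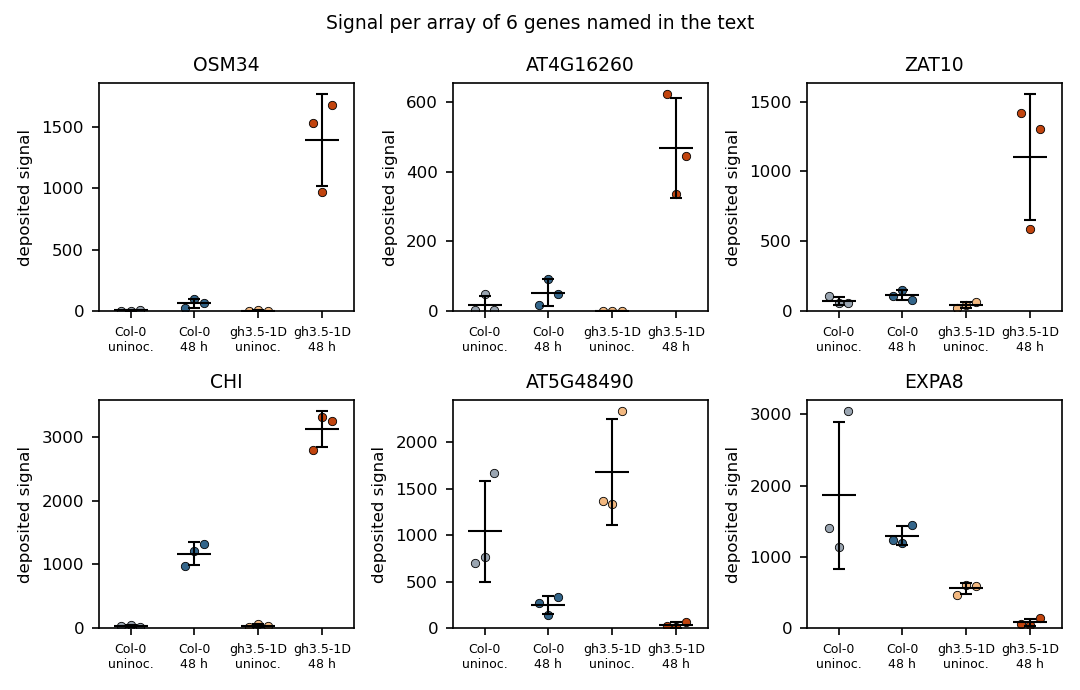
Signal per array (points) of OSM34, AT4G16260, ZAT10, CHI, AT5G48490 and EXPA8 in the 4 groups, with the mean and SD of 3 arrays. The change after infection differed between the genotypes for all of these genes except CHI, which rose in both and was not called for a difference.

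Without inoculation, gh3.5-1D and Col-0 differed most in GH3.5 itself. Among other genes higher in gh3.5-1D were ZW9 (log2 difference 2.45 ± 0.28, SE, adjusted p = 4.16e-05), the expansin EXPA16 (2.28 ± 0.35, adjusted p = 0.00107), AT3G19100 (2.27 ± 0.42), AT2G37870 (2.17 ± 0.32) and PORB, a protochlorophyllide oxidoreductase of chlorophyll synthesis (1.74 ± 0.28, adjusted p = 0.00148). Lower were AT1G06830 (-3.05 ± 0.33, adjusted p = 1.97e-05), AT3G22240 (-3.03 ± 0.22, adjusted p = 1.55e-07), AT3G45160 (-2.95 ± 0.32), AT5G05960 (-2.78 ± 0.43), the light-harvesting gene LHCB4.3 (-2.30 ± 0.27, adjusted p = 4.61e-05) and HAT2, an auxin-responsive homeobox gene (-2.19 ± 0.27, adjusted p = 6.32e-05). LHCB4.3 signal was 280 ± 0.7 in Col-0 and 55.2 ± 21.3 in gh3.5-1D (mean, SD, n = 3). The defensins PDF1.2 (-4.90 ± 0.79, adjusted p = 0.00157) and PDF1.2b (-4.92 ± 0.93, adjusted p = 0.00562) were lower too, with a PDF1.2 signal on single Col-0 arrays that ran from 136 to 3591.7.

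Of the 11 photosynthesis genes, LHCB4.3 was the only one called without inoculation, over all genes and adjusted over the list alone. The set was lower (mean -0.33, camera adjusted p = 0.0364, adjusted p = 0.55 with an estimated correlation, 0.004 to 0.952 over 25 camera alternatives), but this held in 13 of those and not after quantile normalisation (mean -0.13). Among single arrays, it was lost without Col-0 uninoculated replicate 1 (mean -0.32), Col-0 uninoculated replicate 3 (-0.25), gh3.5-1D uninoculated replicate 2 (-0.29), gh3.5-1D uninoculated replicate 3 (-0.35) or Col-0 48 h replicate 3 (-0.33). EXPA8 was lower (-1.60, adjusted p = 0.0142), but not past the threshold without Col-0 uninoculated replicate 3 (-1.18) or gh3.5-1D uninoculated replicate 1 (-1.48). None of the 4 immune receptor and signalling genes, none of 3 salicylic acid genes and none of 3 reference genes passed the test over all genes (salicylic acid genes: median 0.001, mean -0.30, camera adjusted p = 0.496; reference genes: 1 higher and 1 lower adjusted over the list alone, mean 0.11 with a test direction down, camera adjusted p = 0.993). Of 4 expansins and xyloglucan endotransglucosylases 1 was higher and 2 lower (camera adjusted p = 0.431), of which the higher one and 0 of the lower kept their call without any 1 array. Of 4 GH3 genes 1 was higher (camera adjusted p = 0.135), and of 3 endoplasmic reticulum chaperones 1 was higher, 2 adjusted over the list alone (camera adjusted p = 0.107). That chaperone, CNX2 (0.93, adjusted p = 0.0477), was called in 4 of 12 fits that leave out 1 array, those without Col-0 uninoculated replicate 1 or any Col-0 48 h array. In the other 8 it ran from 0.825 to 0.95, with an adjusted p of up to 0.192. Of 5 control ratios, the log2 3' to 5' ratios of both GAPDH controls (0.75 against 1.03 and -0.30 against -0.21, n = 3, exact permutation p = 0.1 each) and of ubiquitin (1.47 against 1.84, n = 3, exact permutation p = 0.1) were lower in gh3.5-1D, beside all of these groups. The 2 actin controls differed by -0.27 and -0.12 (n = 3, exact permutation p = 0.2 and 0.8).

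In all, 665 genes were called without inoculation, 341 higher and 324 lower in gh3.5-1D. The count was 167 without gh3.5-1D uninoculated replicate 1, 186 without gh3.5-1D uninoculated replicate 2, 194 without Col-0 uninoculated replicate 2, 393 without Col-0 uninoculated replicate 3 and 1857 without Col-0 48 h replicate 3. The share of higher genes was 51.3% as deposited, 34.7% after quantile normalisation and 18.9% after median centring, and the median log2 difference of all genes moved from 0.16 to 0.03 and -0.06.

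At 48 h the genotypes differed more widely. Besides GH3.5 the genes highest in gh3.5-1D were OSM34 (log2 difference 4.48 ± 0.40, SE, adjusted p = 5.45e-07), AT3G02480, a late embryogenesis abundant protein (4.01 ± 0.54, adjusted p = 5.98e-05), AT4G33150, a lysine degradation enzyme (3.72 ± 0.29, adjusted p = 1.25e-07), AT5G39520 (3.55 ± 0.40) and AT2G38240, an oxygenase family member (3.47 ± 0.26). ZAT10 (3.16), ChiC (2.71), the dehydrin COR47 (1.95), EIN3, a transcription factor of ethylene signalling (1.60), and CHI (1.42) were also higher. Lower in gh3.5-1D were AT5G22580 (-4.28 ± 0.31, adjusted p = 5.85e-08), EXPA8 (-4.02 ± 0.35, adjusted p = 4.21e-07), AT3G26960 (-3.99 ± 0.28, adjusted p = 5.55e-08), AT5G50915 (-3.34 ± 0.32), AT5G44020 (-3.26 ± 0.23), IAA29 (-2.07 ± 0.32) and GC1 (-1.84 ± 0.33). PDF1.2 (-3.10, adjusted p = 0.00898) and PDF1.2b (-3.43, adjusted p = 0.0123) were lower, but PDF1.2 not past the threshold without gh3.5-1D 48 h replicate 2 (-2.63), nor PDF1.2b without gh3.5-1D 48 h replicate 1 (-2.92).

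Of the 11 photosynthesis genes 5 were lower in gh3.5-1D at 48 h, and 8 adjusted over the list alone, among them LHCB4.3 (-1.85, adjusted p = 0.00014) and PSAN, of photosystem I (-0.71, adjusted p = 0.0142). PSAN was not past the threshold without Col-0 48 h replicate 1 (-0.55), without gh3.5-1D 48 h replicate 1 (-0.68) or after quantile normalisation (-0.31, adjusted p = 0.148), and lay at -0.91 after median centring. Of the 5, only LHCB4.3 kept its call in all 12 fits that leave out 1 array, and only 1 after quantile normalisation. The set was lower (mean -0.55, camera adjusted p = 0.000864, adjusted p = 0.432 with an estimated correlation, 5.72e-05 to 0.477 over 25 camera alternatives) and was called in 23 of those, but not after quantile normalisation (mean -0.20). Of 4 immune genes 2 were higher, over all genes and adjusted over the list alone, PUB23 (1.90, adjusted p = 0.0044) and BIK1 (1.09, adjusted p = 0.00633), and the set was not called (camera adjusted p = 0.177). Of 4 GH3 genes 2 were higher, GH3.5 and GH3.3, over all genes and adjusted over the list alone (camera adjusted p = 0.052). JMT was higher (1.23, adjusted p = 0.00819). Of the 3 reference genes UBC21 was lower (-0.82, adjusted p = 0.0219; 1 of 3 over all genes, 2 higher and 1 lower adjusted over the list alone), but not past the threshold without Col-0 48 h replicate 2 (-0.73), gh3.5-1D 48 h replicate 1 (-0.77) or gh3.5-1D 48 h replicate 2 (-0.81). Of 4 expansins and xyloglucan endotransglucosylases 1 was higher and 1 lower (median 0.34, mean -0.58, camera adjusted p = 0.571). The higher one, EXPA16 (1.01, adjusted p = 0.0437), was called in 4 of 12 fits that leave out 1 array, those without any uninoculated Col-0 array or Col-0 48 h replicate 3, and ran from 0.86 to 1.03 in the others, with an adjusted p of up to 0.123. Of 3 endoplasmic reticulum chaperones 2 were higher, 3 adjusted over the list alone (camera adjusted p = 0.202). Each of the 2 was called in only 3 of those fits. CNX2 (0.73) was kept without Col-0 uninoculated replicate 1 or 3 or Col-0 48 h replicate 3, and ran from 0.56 to 0.82 in the others (adjusted p up to 0.173). CRT2 (0.98) was kept without Col-0 uninoculated replicate 2 or 3 or Col-0 48 h replicate 3, and ran from 0.68 to 1.06 in the others (adjusted p up to 0.212). Of 5 control ratios, the log2 3' to 5' ratio of 1 actin control was lower in gh3.5-1D (1.31 against 1.56, n = 3, exact permutation p = 0.1), beside all of these groups. The second actin control differed by -0.07 (n = 3, exact permutation p = 1.0), and the other 3 ratios gave exact permutation p of 0.3 to 0.9.

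In all, 3741 genes were called at 48 h, 2294 higher and 1447 lower in gh3.5-1D. The count was 2077 without gh3.5-1D 48 h replicate 1, 2320 without gh3.5-1D 48 h replicate 2, 2311 without Col-0 48 h replicate 1 and 2369 without Col-0 48 h replicate 2. The share of higher genes was 61.3% as deposited, 48.6% after quantile normalisation and 40.9% after median centring, and the median log2 difference of all genes moved from 0.17 to 0.03 and -0.03.

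The genotype contrasts at the 2 times share no array. Over 15376 genes their log2 differences correlated with r = 0.502 and rho = 0.514. At both times 152 genes were higher and 198 lower, where independent lists would share 50.9 and 30.5, and 15 genes were called in opposite directions. These calls, too, share the variance of each gene from the same fit and are not independent. Of the 665 genes called without inoculation, 577 (86.8%) had the same sign at 48 h. Averaged over both times, gh3.5-1D exceeded Col-0 most in GH3.5 (7.71 ± 0.25, adjusted p = 3.45e-13), AT3G02480 (2.79 ± 0.38) and the chloroplast-encoded psaA (2.57 ± 0.59, adjusted p = 0.00373). AT4G33150 (2.17 ± 0.20), AT4G23680 (2.07 ± 0.31) and OSM34 (2.07 ± 0.28) followed. The infection response of OSM34 differed between the genotypes by 4.835 (log2), so its average stands for unlike differences at the 2 times. Among chloroplast-encoded genes 5 were higher and 8 lower, and 2 and 4 of these kept their call without any 1 array. Lower in gh3.5-1D were PDF1.2b (-4.18 ± 0.66), PDF1.2 (-4.00 ± 0.56), AT5G22580 (-3.44 ± 0.22, adjusted p = 9.5e-09), AT3G26960 (-3.07 ± 0.20), AT5G05960 (-2.90 ± 0.31) and EXPA8 (-2.81 ± 0.24). Of 11 photosynthesis genes 4 were lower, and 6 adjusted over the list alone, including LHCB4.3 (-2.07) and PSBW (-0.51, but -0.22 and not called after quantile normalisation). Of the 4, 3 kept their call without any 1 array and 1 after quantile normalisation. The set was lower (camera adjusted p = 0.00121, adjusted p = 0.493 with an estimated correlation, 0.000114 to 0.599 over 25 camera alternatives), but not after quantile normalisation (mean -0.16). All 3 endoplasmic reticulum chaperones were higher, over all genes and adjusted over the list alone, among them CNX2 (0.83, adjusted p = 0.00274) and ERDJ3B (0.54, adjusted p = 0.00914), while the set was not called (camera adjusted p = 0.122). The third, CRT2 (0.77, adjusted p = 0.0214), was lost without Col-0 uninoculated replicate 2 (0.63), gh3.5-1D uninoculated replicate 1 (0.74), or Col-0 48 h replicate 1 (0.62) or 2 (0.66). After median centring 1 of the 3 was called. Of the reference genes, UBC21 was lower (-0.81, adjusted p = 0.00241) and SAND higher (0.69, adjusted p = 0.00598), the latter not after median centring (0.48). Beside all of these groups, 3 of 5 log2 3' to 5' control ratios were lower in gh3.5-1D by at least 0.25 at both times. These were 1 GAPDH control (-0.27 uninoculated and -0.30 at 48 h, n = 3, exact permutation p = 0.1 and 0.3), ubiquitin (-0.38 and -0.36, n = 3, exact permutation p = 0.1 and 0.4) and 1 actin control (-0.27 and -0.25, n = 3, exact permutation p = 0.2 and 0.1). The second GAPDH control differed by -0.09 and -0.02 (n = 3, exact permutation p = 0.1 and 0.9) and the second actin control by -0.12 and -0.07 (n = 3, exact permutation p = 0.8 and 1.0).

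In all, 5028 genes differed between the genotypes averaged over both times, 3240 higher and 1788 lower in gh3.5-1D, and no single array moved that count by over 1.5 times. The share of higher genes was 64.4% as deposited, 48.6% after quantile normalisation and 37.3% after median centring, and the median log2 difference of all genes moved from 0.18 to 0.04 and -0.04.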

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

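A difference between groups flagged every result in this part: the test of whether the infection change in gh3.5-1D differs from that in Col-0, which called 344 genes. The test was fixed before the values were seen. The tests below were fixed before their results were seen, except that of a batch shared by the arrays numbered 3, which was chosen only after its pattern was seen.

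The 21 flagged genes that the text names are those the naming rule gives. Their log2 difference of the infection response, gh3.5-1D minus Col-0, was positive for OSM34 (4.835), AT4G16260 (4.558), AT1G09500 (4.204), ZAT10 (3.995), AT4G39670 (3.727), AT1G30700 (3.588), CML23 (2.982), ChiC (2.792), GH3.3 (2.367), CYP71B23 (1.52), UGT87A2 (1.44), EXPA4 (1.42) and UGT78D2 (1.41). It was negative for EXPB1 (-1.75), EXPA8 (-2.413), AT4G28780 (-2.825), AT4G09840 (-2.88), AT2G10940 (-2.95), AT5G20740 (-3.02), AT1G67750 (-3.50) and AT5G48490 (-3.61). Fits that leave out 1 array kept the call of 14 of these 21 in all 12. The 2 flagged lists, both written after the annotation was read and before any group comparison was computed, are the chloroplast-encoded genes (mean difference -0.406) and the extended photosynthesis genes (mean difference -0.324), and neither was called with an estimated correlation (adjusted p = 0.879 and adjusted p = 0.418 with an estimated correlation).

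Counts under other splits of the arrays were as follows. For infection in Col-0 the real split called 602 genes and the highest other split 0, for infection in gh3.5-1D 5425 and 0, for genotype without inoculation 1199 and 0, and for genotype at 48 h 2936 and 0. In each of these, 1 split of 10, the real one, called as many, and 10 splits are too few for this test. For the difference in infection response, 13 splits of 200 called at least the 344 of the real labels, the highest other calling 5028. In 11 of these, exchanging the labels of a whole time turns the tested difference into the genotype contrast averaged over both times, with at most 2 arrays otherwise moved. Among the 100 splits without such an exchange 2 called as many, the real one and one with 383. Since the splits carry the genotype difference, they do not test the difference in response alone, and whether chance can be excluded stays open. For genotype averaged over both times, only the real split of 200 (1) reached 5028, the highest other calling 2922. This argues against chance, provided that the arrays of a time can be exchanged for each other.

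The first pattern is a larger infection response in gh3.5-1D than in Col-0. Were it due to 1 weakly responding Col-0 array, another Col-0 array would reach the gh3.5-1D arrays, but over 1017 genes called in both genotypes the highest Col-0 array had a mean signed change of 1.709 and the lowest gh3.5-1D array 2.119. A shift of whole arrays by the scaling would move rises and falls the same way, but the falls differed by -0.465 and the rises by 0.775. Both values speak against these technical explanations, and a biological one, such as the genotype or a more severe infection, may hold but was not tested, since bacterial numbers are not used here.

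The second pattern is more genes higher than lower in gh3.5-1D averaged over both times. The share of higher genes was 64.4% as deposited, 48.6% after quantile normalisation and 37.3% after centring each array on its median. The split thus changes with the scaling, and whether the authors' scaling or a true rise of many transcripts gives it could not be told from these arrays. The control ratios of RNA quality given above were also lower in gh3.5-1D at both times, by differing amounts, and their part in this pattern was not tested.

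The third pattern is the Col-0 array at 48 h numbered 3, which stood apart on the second principal component (12.7 against 68.5 and 68.1). An uninoculated sample under a wrong name would show no infection response, but its mean signed change over the genes called in gh3.5-1D was 0.658, where the highest uninoculated Col-0 array had 0.06. A weaker infection response would put it below the other Col-0 arrays at 48 h; over rises and falls together it lay 0.039 above the lower of them, which differ by 0.198, but over the 382 falls shared by the genotypes its mean change was the weakest (-1.037 against -1.209 and -1.398) and it correlated with the uninoculated Col-0 arrays as with its own group (mean 0.905 each), so a weaker response in part of the genes stays open. A handling batch shared by the arrays numbered 3 remains possible: its deviation correlated with those of the other 3 at -0.042 (gh3.5-1D uninoculated), 0.237 (gh3.5-1D 48 h) and 0.317 (Col-0 uninoculated), the other pairs of these 4 arrays at 0.186, 0.305 and 0.342, and on the third principal component the 4 scored 6.9 to 50.2 and the 8 other arrays -31.7 to -5.4. A difference in the plants themselves could also give it and was not tested.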

How the results depend on the processing

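Among alternatives for single named genes, 7675 of 8345 values kept direction and call, 662 lost the call, 8 gained it and 0 reversed. Each value is 1 gene in 1 setting, and genes that stayed uncalled count as kept. Counted per called gene, fewer held in all settings: 26 of 45 for infection in Col-0, 63 of 76 for infection in gh3.5-1D and 15 of 30 for genotype uninoculated. For genotype at 48 h it was 45 of 82, for the difference in response 10 of 21 and for genotype averaged 55 of 79. For lists 3499 of 3732 values kept both, 135 lost the call, 93 gained it and 5 reversed. All 5 are means of the chloroplast-encoded genes (leaving out 1 array in turn, -0.809 to 0.131, -0.915 to 0.026 and -0.117 to 0.309 in the 3 contrasts below): infection in Col-0 gave 0.131 without Col-0 48 h replicate 3, the infection response between genotypes 0.026 without Col-0 uninoculated replicate 3, and genotype averaged over both times -0.078 without Col-0 uninoculated replicate 3, -0.117 without Col-0 48 h replicate 3 and -0.332 without the 2 Col-0 arrays numbered 3. The GH3.5 difference kept its direction and call under every setting. Unless stated otherwise the cause was not tested. Settings that leave out several arrays numbered 3 were chosen after seeing the data.

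Counts of genes are given in the order infection in Col-0, infection in gh3.5-1D, genotype uninoculated, genotype at 48 h, difference in response and genotype averaged, where they moved by over 1.5 times. Array weights gave 1993, 6697, 3526, 5746 and 1004 for the first 5. Without the 4 arrays numbered 3 they were 2945, 2394, 5867 and 1077 (infection in Col-0, genotype uninoculated, genotype at 48 h, difference in response), and without the 2 Col-0 arrays numbered 3 they were 2416, 1726, 5920 and 939. An adjusted p under 0.01, stricter by construction, gave 539, 2606, 143, 1721, 131 and 2533. A log2 change of at least 1 gave 2371 at 48 h and 1297 averaged. A fit of only the 2 groups compared gave 602 for infection in Col-0 and 1199 for genotype uninoculated. Genotype uninoculated was 433 with no filter and 290 without trend, and the difference in response 223 with pseudocount 0.

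Leaving out 1 array in turn gave 652 to 2573 for infection in Col-0, 3046 to 4780 for infection in gh3.5-1D, 167 to 1857 for genotype uninoculated, 2077 to 5281 for genotype at 48 h, 175 to 705 for the difference in response and 3629 to 6391 for genotype averaged. The share of higher genes, 58.1% for infection in Col-0 and 51.3% for genotype uninoculated, ran from 39.2% to 69.7% and from 29% to 64.1% in these fits, and array weights gave 911 higher and 1082 lower for infection in Col-0. An arm left with 2 arrays borrows its spread from the other groups. The correlation of the infection responses was 0.643 to 0.716 in these fits, 0.601 with no filter, 0.62 without the 4 arrays numbered 3 and 0.626 without the 2 Col-0 ones.

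In the fit with a replicate block, which pairs arrays by number, the counts were 1767, 4737, 1694, 4635, 659 and 5843. For infection in Col-0, the numbers were taken to pair the arrays. Yet Col-0 48 h replicate 1 correlates better with uninoculated replicate 2 (0.147) than with its own number (0.108). In that contrast the block gave 933 genes higher and 834 lower, against 713 and 515 in the main fit. No list called there in the main fit lost its call with the block. In every other comparison at least 1 same-numbered pair correlates under 0.1, and in none does every array correlate best with its own number. Their block fit is given only here. For infection in gh3.5-1D the defensin list, called in the main fit, lost its call with the block (camera adjusted p = 0.0518). That list was called in only 8 of 25 camera alternatives, with a camera adjusted p of 0.0172 to 0.349.

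Of 24 lists, the number called for infection in Col-0 (8) was 2 with the stricter filter, 5 without trend, 4 with array weights, 5 without the 4 arrays numbered 3, 4 without the 2 Col-0 ones, 0 with an estimated correlation, and 3 to 8 leaving out 1 array. For infection in gh3.5-1D (8) it was 0 with an estimated correlation, 20 with fry and 7 to 11 leaving out 1 array. For genotype uninoculated (3) it was 0 with the stricter filter, quantile normalisation, no trend, array weights, either set of arrays numbered 3 left out and an estimated correlation, 1 with fry and 0 to 4 leaving out 1 array. At 48 h (2) it was 6 with the larger pseudocount, 0 with quantile normalisation, 4 with array weights, 4 with either set left out, 0 with an estimated correlation, 8 with fry and 2 to 6 leaving out 1 array. For the difference in response (2) it was 1 with pseudocount 0, 0 with quantile normalisation, 1 without trend, 4 without the 4 arrays numbered 3, 0 with an estimated correlation and 0 to 5 leaving out 1 array. For genotype averaged (2) it was 0 with quantile normalisation, 1 without the 4 arrays numbered 3, 0 with an estimated correlation, 10 with fry and 2 to 4 leaving out 1 array. Robust moderation was not run for lists, as camera has no such option.

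Signal over background limits genes near the floor of 16.1, among them GH3.5 in Col-0, whose difference was 6.851 with the larger pseudocount and 8.614 with pseudocount 0, uninoculated.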

Other observations

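The gene groups in this part were written after the annotation was read and before any group comparison was computed. Of 22 genes in the extended photosynthesis list 9 fell after infection in gh3.5-1D, among them NdhN (log2 change -1.39, adjusted p = 6.61e-05), LPA19 (-1.15) and LPA2 (-1.13), and the list was lower as a set (mean -0.59, camera adjusted p = 0.000523, adjusted p = 0.179 with an estimated correlation, 6.84e-05 to 0.179 over 25 camera alternatives). Of 11 genes of tetrapyrrole and chlorophyll metabolism 6 fell, and 7 adjusted over the list alone, including CHLM (-0.95, adjusted p = 0.00643) and HEME2 (-0.94, adjusted p = 0.00456) (camera adjusted p = 0.014, adjusted p = 0.344 with an estimated correlation, 0.00178 to 0.344 over 25 camera alternatives). Of 6 tubulins 4 fell, among them TUB7 (-2.29, adjusted p = 7.63e-06) and TUB6 (-1.74, adjusted p = 0.000594) (camera adjusted p = 0.0161, adjusted p = 0.349 with an estimated correlation, 0.00178 to 0.349 over 25 camera alternatives). Without any 1 array 8 of those 9, 4 of those 6 and 3 of those 4 kept their call. In Col-0 the extended photosynthesis list was also lower (1 of 22 fell, mean -0.26, camera adjusted p = 0.033, adjusted p = 0.349 with an estimated correlation, 0.0128 to 0.364 over 25 camera alternatives), but not without Col-0 uninoculated replicate 3 (-0.22) or Col-0 48 h replicate 3 (-0.25). So were the tubulins (2 of 6 fell, mean -0.64, camera adjusted p = 0.0287, adjusted p = 0.349 with an estimated correlation, 0.00529 to 0.349 over 25 camera alternatives), but not without Col-0 48 h replicate 1 (-0.58) or 2 (-0.48). Of the 2 that fell, TUB9 (-0.93) was called in 4 of 12 fits that leave out 1 array (without Col-0 uninoculated replicate 3, Col-0 48 h replicate 1, or gh3.5-1D uninoculated or 48 h replicate 3; -0.93 to -0.76 in the others) and TUB7 (-1.26) in 11, lost without Col-0 48 h replicate 2 (-0.99). The 1 photosynthesis gene, SBPASE (-0.77), was lost without Col-0 uninoculated replicate 1 (-0.70) or 2 (-0.77) or Col-0 48 h replicate 2 (-0.61).

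Of 10 autophagy genes 3 rose after infection in gh3.5-1D, and 6 adjusted over the list alone, among them ATG8D (1.82, adjusted p = 0.000155), APG8A (1.44, adjusted p = 0.000304) and ATG8H (1.28, adjusted p = 0.00184) (camera adjusted p = 0.00736, adjusted p = 0.349 with an estimated correlation, 0.00107 to 0.349 over 25 camera alternatives). Without inoculation the same list was lower in gh3.5-1D than in Col-0, with 0 of 10 called (mean -0.36, camera adjusted p = 0.0364, adjusted p = 0.55 with an estimated correlation, 0.0112 to 0.55 over 25 camera alternatives). That call held in 15 of those, but not after quantile normalisation (mean -0.43), with the stricter filter, without the trend or with array weights. Among single arrays, it was lost without Col-0 uninoculated replicate 3 (-0.23), gh3.5-1D uninoculated replicate 1 (-0.21) or Col-0 48 h replicate 3 (-0.36). After infection in Col-0 2 of 10 rose, ATG8D by 1.66 and APG8A by 1.08, the latter lost without Col-0 uninoculated replicate 1 (0.98) or 2 (0.94) or Col-0 48 h replicate 2 (1.035) (camera adjusted p = 0.00341, adjusted p = 0.349 with an estimated correlation, 0.000149 to 0.349 over 25 camera alternatives). At 48 h 10 of 27 UDP-glycosyltransferases were higher in gh3.5-1D, and 12 adjusted over the list alone, among them UGT76E11 (1.45, adjusted p = 0.000479) and UGT87A2 (1.41, adjusted p = 0.000588); the set had a camera adjusted p = 0.052, and an adjusted p = 0.226 with an estimated correlation. Of the 10, 5 kept their call without any 1 array, 6 after quantile normalisation and 5 after median centring. In Col-0, the vacuolar protease GAMMA-VPE rose after infection (1.00, adjusted p = 0.00387). After infection in gh3.5-1D 1 vacuolar processing enzyme rose too, and at 48 h 2 were higher there than in Col-0.

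The hybridisation spikes of the Col-0 arrays numbered 3 had mean log2 signals of 10.129 uninoculated and 9.961 at 48 h. Those of the gh3.5-1D arrays numbered 3 had 9.509 and 9.596, within the range of the 8 other arrays (9.311 to 9.859). On the third principal component the Col-0 arrays numbered 3 scored 43.4 and 50.2, the gh3.5-1D arrays numbered 3 6.9 uninoculated and 21.4 at 48 h, and the 8 other arrays -31.7 to -5.4.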
